A study of Ovis aries with 14 samples.

How the data were processed

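RNA was measured in perirenal fat, the fat depot around the kidney, of 14 male suckling lambs of the sheep breeds Assaf (8 lambs) and Churra (6 lambs). Total RNA was extracted with a miRNeasy kit and made into libraries with a stranded total RNA kit, per the labels' protocols. FastQC, STAR 2.4.0, RSEM 1.3.0 and the sheep genome build Oar_v3.1 are named in the submitters' processing notes, which give no role or order. The strand setting of the counting step, read trimming and filters are not given in the sources used here.

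There was 1 table per lamb, with the same 27054 Ensembl gene IDs in each. The authors deposited estimated counts per gene (the expected count of RSEM, which shares reads that align to several genes among them), per the file headers. These estimated counts are not normalized, and between 4.80% and 5.40% of genes per lamb had a value farther than 0.005 from a whole number. The deposited TPM values, per the file headers, are length-scaled transcript abundances that sum to the same total in every lamb. The tables also hold the posterior standard deviation of each count, in counts, and the length and effective length of each gene in bases, per the file headers.

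The files pair no gene ID with a gene symbol. None of the IDs (0 of 27054) could be matched to the reference gene table, which is of assembly ARS-UI_Ramb_v3.0 and gives no Ensembl ID for any gene. Gene symbols, positions and functions are therefore not reported, and the 33 gene lists and the tests of single named genes that had been fixed before the data were examined could not be run. The rule for printed genes, fixed at the same time, asked for genes with a symbol. Among these it took genes past the threshold with a mean above 1 log2 CPM in order of p-value. Because the IDs have no names, the symbol condition was dropped afterwards and the number was limited to 2 IDs per direction.

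Each lamb was counted as 1 replicate of its breed, numbered in accession order. The numbers pair no lambs. Total counts ranged from 14152614 to 24370921 per lamb. No pair of lambs of 1 breed agreed within sampling noise. The smallest chi-square per degree of freedom between their counts, over genes with 20 or more counts in the pair, was 27.0. The slaughter day and live weight were taken from the labels. The labels do not say from when the slaughter day is counted, and their lowest value, 17, lies below the youngest age in the series' design text.

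Estimated counts were rounded to whole numbers. Genes with low counts were removed with edgeR's filterByExpr by breed, which left 13197 genes, and library sizes were scaled with TMM factors. The breed difference was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion, breed as the only term, all 14 lambs, two-sided). Genes were called at a Benjamini-Hochberg adjusted p below 0.05, with no fold limit. The change per slaughter day was tested in the same way with breed and day as terms. Standard errors of log2 fold changes are the fold change divided by the square root of F. On simulated counts with 200 changed genes among 13197, the breed test recovered 32.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 3 false calls in 139. DESeq2 made 20 false calls in 167 on the same counts. The slaughter day test recovered 17.9%, 58.2% and 93.9% of genes that changed 1.5-fold, 2-fold and 4-fold over 10 days, with 1 false call in 114. Simulated genes were drawn independently of each other, so these rates do not cover variation that genes of the real lambs share.

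Per-lamb values were the total count, the number of genes with a count above 0, the share of all counts in the 10 genes with the most counts over all lambs, the mean fragment length, and the length slope. The fragment length is the median of length minus effective length plus 1 over single-isoform genes longer than 5000 bases. The length slope is the regression of a lamb's log2 CPM deviation from the gene mean on log2 gene length, without the 20 most abundant genes. Principal components were taken from log2 CPM with a prior count of 2. Breed means of 9 per-lamb values were compared by exact permutation over all 3003 splits of the lambs, two-sided. Correlations across lambs used 100000 random orders for all 14 lambs and exact enumeration within a breed. Intervals of single shares are exact Clopper-Pearson 95% intervals and cover counting error only.

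Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper-quartile factors), no low-count filter or a mean count of 10, DESeq2 1.42.0, limma 3.58.1 (voom, and limma-trend on log2 of the deposited TPM plus 0.5), other covariates (slaughter day, live weight, 2 surrogate variables from sva 3.50.0), lambs of overlapping slaughter days (21 to 23), other thresholds, and each lamb left out in turn. The share of variance between the breeds, the principal components, the counts of separated genes, the per-lamb values and their correlations, with their alternatives (slaughter days 21 to 23, genes scaled to unit variance, the 5 or 20 most abundant genes, the share of TPM, leaving out Assaf 7 with Churra 6), were chosen after the data had been seen. For the tests of single genes, alternatives added later were the length slope as a term, the edgeR likelihood ratio test, the non-legacy edgeR fit, and leaving out Assaf 7 with Churra 6. Mitochondrial genes could not be identified by name, so the alternative meant to remove them with the 20 most abundant genes removed only those 20.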

Results

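The perirenal fat transcriptome was measured by RNA sequencing in 14 male lambs reared on milk replacer and slaughtered at a similar live weight. Of these, 8 were Assaf lambs and 6 were Churra lambs. Live weight averaged 10.3 ± 0.612 kg in Assaf (SD, n = 8) and 10.3 ± 0.816 kg in Churra (SD, n = 6), and the difference had an exact permutation p of 0.988. The slaughter day averaged 21.0 ± 2.33 in Assaf (SD, range 17 to 23) and 26.5 ± 5.72 in Churra (SD, range 21 to 35). That difference of 5.5 days had an exact permutation p of 0.0316, and 0.142 after adjustment over the 9 per-lamb values compared. Breed and slaughter day were thus only partly separable, with 6 Assaf and 3 Churra lambs on the shared days 21 to 23.

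Sequencing depth did not differ between the breeds by more than the spread between lambs, with total counts per lamb of 14827742 to 21084567 in Assaf and 14152614 to 24370921 in Churra (exact permutation p = 0.427). The number of genes with a count above 0 was 16151 ± 177 in Assaf and 16211 ± 114 in Churra (SD, exact permutation p = 0.492). Mean fragment length was 162.8 ± 2.95 bases in Assaf and 164.5 ± 2.39 bases in Churra (SD, exact permutation p = 0.272). Pearson correlations of log2 CPM between lambs lay between 0.946 and 0.981. The median was 0.970 within Assaf, 0.970 within Churra and 0.967 between the breeds, and Churra 6 had a median of 0.954 with the other lambs.

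The first question, given by the series' design text, was how the perirenal fat transcriptome differed between the breeds. Breed accounted for 13.8% of the total variance of log2 CPM over 13197 genes, against a median of 7.45% over all 3003 splits of the lambs (exact permutation p = 0.002). This measure was chosen after the data had been seen. In the lambs of slaughter days 21 to 23 the share was 21.8%, against a median of 12.6% over 84 splits (exact permutation p = 0.0119). The second principal component, with 16.0% of the variance, parted the breeds without overlap. Assaf lambs scored between 6.71 and 20.84 on it and Churra lambs between -53.74 and 0.26. The exact permutation p of 0.000333 was the smallest the design can give, and it was 0.003 after adjustment over 9 values. Churra 6 had the lowest score. The Churra lambs slaughtered on the shared days lay farther from Assaf than the later ones, as the 3 of days 21 to 23 scored between -53.74 and -17.36 and the 3 of days 29 to 35 between -7.51 and 0.26. With the slaughter day the score had r of 0.775 within Churra (exact permutation p = 0.0472, unadjusted; rho 0.812, p = 0.0722), 0.253 within Assaf (exact permutation p = 0.533; rho 0.0737, p = 0.867) and -0.0942 over all 14 lambs (permutation p = 0.745, adjusted p = 0.745; rho -0.220, p = 0.446). The first component, with 19.3% of the variance, did not part the breeds (exact permutation p = 0.396). Its score fell with the slaughter day, with rho of -0.681 over 14 lambs (permutation p = 0.00869, adjusted p = 0.0196), and with r of -0.592 (permutation p = 0.0272, adjusted p = 0.0612), which was -0.363 without Churra 1 and Churra 2. Within Churra, rho was -0.928 (exact permutation p = 0.0222) and r was -0.886 (exact permutation p = 0.025), and within Assaf rho was -0.417 (exact permutation p = 0.298) and r was -0.341 (exact permutation p = 0.415).

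**Figure D1:**
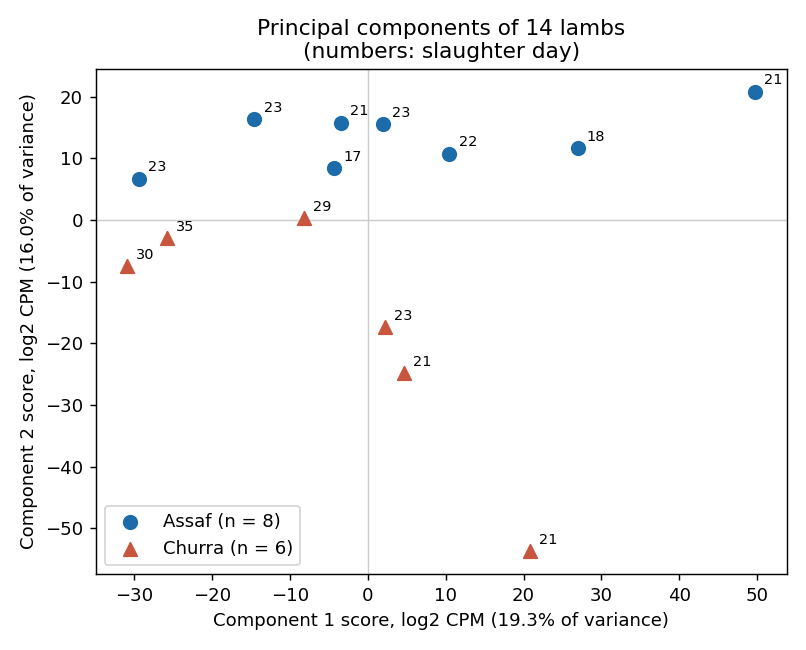
Scores of the 14 lambs on the first (x axis) and second (y axis) principal components of log2 CPM, with circles for Assaf, triangles for Churra and the slaughter day beside each point. All 8 Assaf lambs lie above 6 and all 6 Churra lambs below 1 on the second component, and Assaf 7 lies farthest right at 49.74.

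At the level of single genes, 26 of 13197 genes differed between the breeds (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 16 were higher in Churra, by 1.31-fold to 4.35-fold with a median of 1.89-fold. The other 10 were lower in Churra, by 1.37-fold to 7.54-fold with a median of 2.28-fold. The largest fold in each direction came from a gene with a mean below 1 log2 CPM, while 19 of the 26 genes had a mean above it. The gene with the 7.54-fold change had the smallest edgeR adjusted p, 0.0134, and is not printed below because of its low mean. Changes of 2-fold or more made up 6 of the higher and 5 of the lower genes. For 10 of the 16 higher genes and 7 of the 10 lower genes, no Churra lamb overlapped any Assaf lamb in CPM. The genes were called on the same lambs, so this follows in part from their selection. Over all genes tested, 72 (0.55%) were separated in this way, 34 with Churra higher and 38 with Churra lower, where chance gives 0.0666% or 8.8 genes on average. The number of separated genes was not set against other splits of the lambs. An unadjusted p below 0.05 was reached by 1767 genes (13.4%), with 891 fitted values higher and 876 lower in Churra. Chance gives 660 on average, but 7 of 100 splits of the lambs into 6 and 8, the real one included, gave 1767 or more (highest other 2995), so this count did not stand out from other groupings of the lambs. In limma-trend on log2(TPM + 0.5), 919 genes reached an unadjusted p below 0.05.

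The genes below are given by Ensembl ID, because the files pair no ID with a symbol or a position. ENSOARG00000016570 was 1.45-fold higher in Churra, with 46.2 ± 5.90 CPM (SD, n = 6) against 31.9 ± 2.66 CPM in Assaf (SD, n = 8). Its log2 fold change was 0.53 ± 0.08 (SE, edgeR adjusted p = 0.0379). ENSOARG00000019015 was 1.95-fold higher, at 15.7 ± 1.91 CPM in Churra and 8.05 ± 2.12 CPM in Assaf (log2 fold change 0.97 ± 0.15 SE, edgeR adjusted p = 0.0379). Among the lower genes, ENSOARG00000001626 was 1.87-fold higher in Assaf, at 6.49 ± 1.21 CPM against 3.47 ± 0.530 CPM in Churra (log2 fold change -0.90 ± 0.14 SE, edgeR adjusted p = 0.0379). ENSOARG00000004167, the most highly expressed of these 4 genes, reached 113.6 ± 13.3 CPM in Assaf and 73.9 ± 11.3 CPM in Churra, a 1.54-fold difference (log2 fold change -0.62 ± 0.10 SE, edgeR adjusted p = 0.0379). In each of the 4 genes, which were chosen by p-value on the same lambs, every Churra lamb lay on 1 side of every Assaf lamb.

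**Figure D2:**
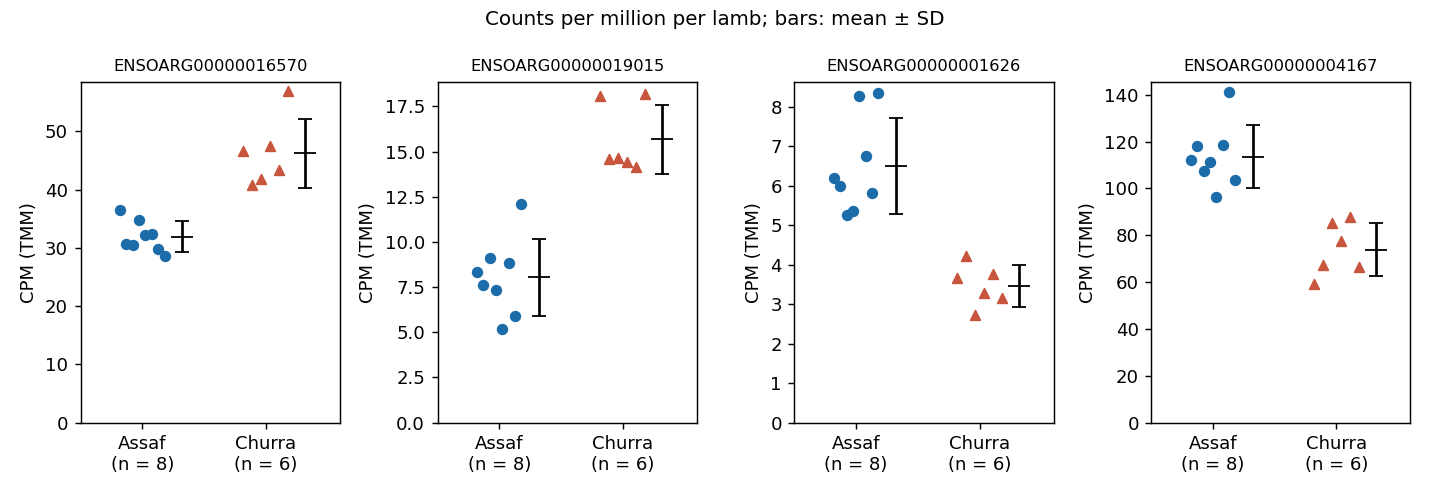
CPM after TMM scaling (y axis, from 0) of the 4 genes in each lamb, with circles for Assaf (n = 8), triangles for Churra (n = 6) and bars for the mean ± SD. ENSOARG00000016570 lies between 40.9 and 57.0 CPM in Churra and between 28.6 and 36.5 CPM in Assaf, and none of the 4 genes shows an overlap of the breeds.

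The directions of these 26 genes did not turn when slaughter day was taken into account. With the day as a term, all 26 kept their sign and an unadjusted edgeR p below 0.05, while 13 genes over the whole transcriptome passed the adjusted threshold (6 higher and 7 lower in Churra), 5 of them among the 26. In the 9 lambs of slaughter days 21 to 23, which are part of the same data, the 26 again kept their sign and an unadjusted edgeR p below 0.05. Only 1 gene passed the adjusted threshold there, and it was not among the 26. ENSOARG00000016570 had a log2 fold change of 0.60 with the day as a term (edgeR adjusted p = 0.0260) and 0.64 on the shared days (edgeR adjusted p = 0.0771). ENSOARG00000019015 had 1.01 (edgeR adjusted p = 0.0688) and 1.09 (edgeR adjusted p = 0.102). For ENSOARG00000001626 the values were -0.89 (edgeR adjusted p = 0.0838) and -0.87 (edgeR adjusted p = 0.182), and for ENSOARG00000004167 they were -0.53 (edgeR adjusted p = 0.0974) and -0.58 (edgeR adjusted p = 0.212).

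**Figure D3:**
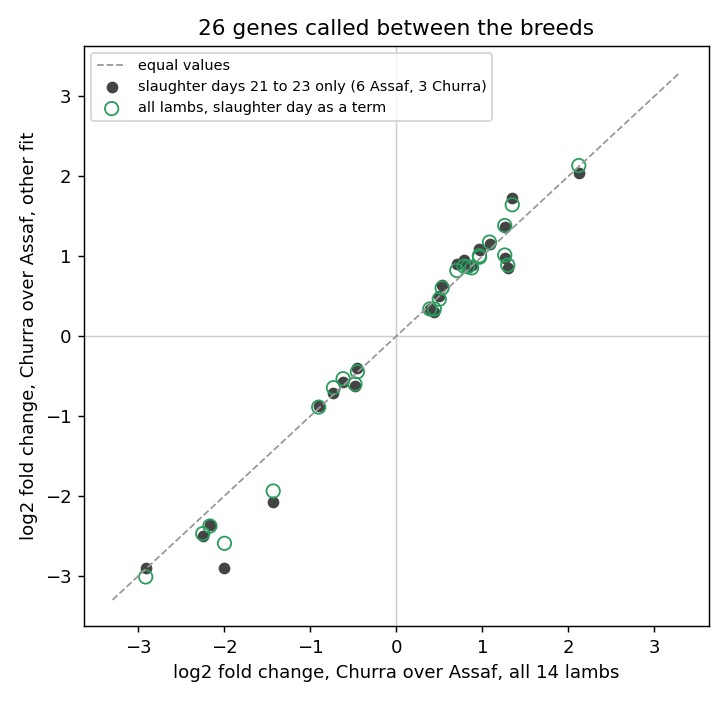
Log2 fold change (Churra over Assaf) of the 26 genes in all 14 lambs (x axis) against the value in another fit (y axis), with filled points for slaughter days 21 to 23 only, open circles for all lambs with the day as a term and a dashed line for equal values. All 26 genes lie in the same quadrant in both fits.

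The number of genes called depended on the lambs included and on the tool. The count of 26 fell to 0 without Churra 4 (1634 genes at an unadjusted edgeR p below 0.05), to 1 without each of Assaf 2, Assaf 5, Churra 1 and Churra 6, to 2 without Assaf 1, to 4 without Assaf 4, to 5 without Churra 2, to 9 without Churra 5, to 15 without Assaf 8, and to 17 without each of Assaf 3 and Churra 3. It was 12 without both Assaf 7 and Churra 6, the lambs farthest out on the first and second components. DESeq2 called 371 genes on the same counts, 181 higher and 190 lower in Churra, which included all 26, and 3 of 50 splits, the real one included, gave as many.

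The second question, set by the slaughter day in the labels, was whether gene expression changed with that day within the breeds. No gene passed the threshold (0 of 13197, smallest edgeR adjusted p = 0.191). An unadjusted edgeR p below 0.05 was reached by 2156 genes (16.3%), 976 with a positive and 1180 with a negative slope, against 660 from chance. Fitted within 1 breed, the number was 2299 in Churra lambs only and 439 in Assaf lambs only, the latter below the 660 from chance. In all lambs it was 1170 without Churra 6, 448 with 2 surrogate variables as terms, and 662 with each lamb's length slope, described with the last comparison, as a further term. It rose to 3794 in limma-trend on log2(TPM + 0.5), to which no scaling between lambs was applied. TPM are shares of a fixed total, so that count can also reflect the abundant genes described with the last comparison. The median fitted slope of the 2156 genes, in size, was 1.40-fold over 10 days. Of these genes, 227 also had an unadjusted p below 0.05 between the breeds, where 289 would overlap if the lists were independent. The breed p came from the fit without the day and the day p from the fit with both terms. The lists need not be independent for that reason, so the overlap cannot show whether breed and day effects are related. Limma voom called 0 genes for the day (2204 at an unadjusted p below 0.05), and DESeq2 called 156, 59 rising and 97 falling.

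A large part of all counts came from a few genes, and that part differed between lambs. The 10 most abundant genes took 29.3 ± 7.96% of counts in Assaf (SD, n = 8) and 26.8 ± 5.55% in Churra (SD, n = 6), which did not differ by more than the spread between lambs (exact permutation p = 0.540). Single lambs ranged from 18.0% in Assaf 3 (exact Clopper-Pearson 95% interval 18.027% to 18.063%) to 45.2% in Assaf 7 (45.158% to 45.201%). Across all 14 lambs the share fell with the slaughter day, with Spearman's rho of -0.740 (permutation p = 0.00334, adjusted p = 0.01 over 9 relations). Pearson's r was -0.538 (permutation p = 0.0532, adjusted p = 0.0958), and -0.296 without Churra 1 and Churra 2, the lambs with the days farthest from the median, so the linear relation rested on those lambs. Within Churra, rho was -0.986 (exact permutation p = 0.00556) and r was -0.879 (exact permutation p = 0.0111). Within Assaf, rho was -0.589 (exact permutation p = 0.129) and r was -0.361 (exact permutation p = 0.383). Whether the relation differed between the breeds was not tested.

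**Figure D4:**
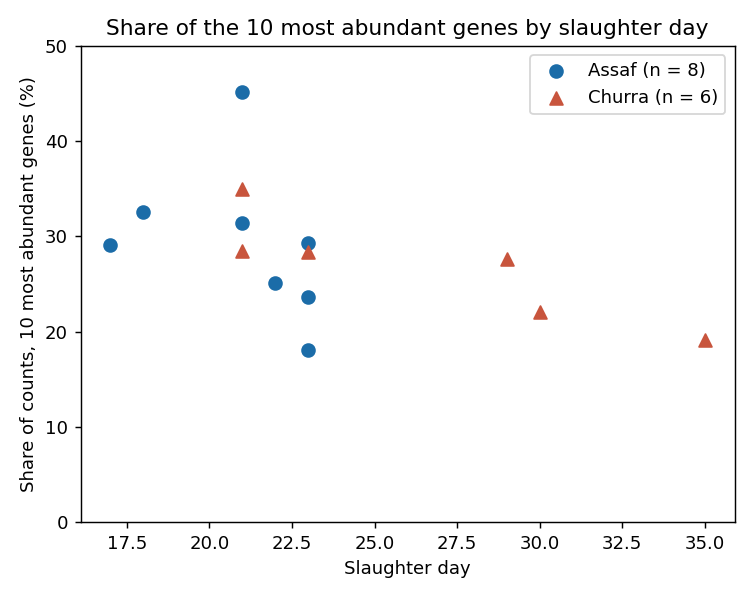
Share of all counts in the 10 most abundant genes, in percent (y axis, from 0), against slaughter day (x axis) for each lamb, with circles for Assaf (n = 8) and triangles for Churra (n = 6). The Churra lambs run from 34.98% on day 21 to 19.11% on day 35, and Assaf 7 stands highest at 45.18%.

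Lambs in which the 10 genes took a larger share also had lower values of long genes relative to short ones among the remaining genes. The length slope and the share had Pearson's r of -0.811 (permutation p = 0.00022, adjusted p = 0.00099) and rho of -0.824 (permutation p = 0.00056, adjusted p = 0.00252) over 14 lambs. Without Assaf 7 and Churra 2 the r was -0.777, and it was -0.829 within Assaf (exact permutation p = 0.00769) and -0.850 within Churra (exact permutation p = 0.0292). The length slope did not differ between the breeds by more than the spread between lambs (exact permutation p = 0.749). The share also followed the first principal component, with r of 0.918 (permutation p = 2e-05, adjusted p = 0.00018) and rho of 0.820 (permutation p = 0.00044, adjusted p = 0.00252). That r was 0.825 without Assaf 3 and Assaf 7, 0.904 within Assaf (exact permutation p = 0.00305) and 0.952 within Churra (exact permutation p = 0.00972).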

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

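The count of 26 genes between the breeds lay within 1.5 times of its value with DESeq2 size factors in edgeR, with a mean count of 10 or more, with limma voom, with the non-robust and non-legacy edgeR fits and without the 20 most abundant genes. It fell to 17 with upper-quartile factors, 13 with no low-count filter, 12 with live weight added, 13 with slaughter day added, 13 with slaughter day and live weight added, 1 on slaughter days 21 to 23 only, 10 with limma-trend on log2(TPM + 0.5), 0 at an adjusted threshold of 0.01 and 12 without Assaf 7 and Churra 6. It rose to 112 at an adjusted threshold of 0.10, 59 with 2 surrogate variables, 96 with the length slope added, 257 with the edgeR likelihood ratio test and 371 with DESeq2. With 1 lamb left out it lay between 0 (without Churra 4, 1634 genes at an unadjusted p below 0.05) and 24 (without Assaf 7). The cause of these shifts was not tested. The 4 genes printed by ID kept their direction in all 32 alternatives each (0 reversed), and lost the adjusted call in 7 of them for ENSOARG00000016570, in 13 for ENSOARG00000019015, in 11 for ENSOARG00000001626 and in 13 for ENSOARG00000004167, with adjusted p of at most 0.274. For the slaughter day the count of 0 became 156 with DESeq2, and between 0 and 1 with 1 lamb left out (1 without Assaf 5 and 1 without Assaf 6). It stayed at 0 under the other alternatives run, limma included. The share of variance between the breeds and the rho of the 10-gene share with the day kept their direction and side of the threshold under each alternative run. With genes scaled to unit variance, however, the share of variance was 11.7%, against a median of 7.27% over the splits. Its exact permutation p was then 0.042, close to the threshold. The gene list tests and the single-gene correlation with the day planned before the data were examined were not run, for want of gene symbols. At the real depths and numbers of lambs, simulated breed changes of 4-fold were recovered in 95.5% of genes and those of 1.5-fold in 32.8%, so small changes can be missed. Depth was not varied in that simulation, and its genes were drawn independently of each other.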

Other observations

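The tests of the length slope, the depth, the slaughter day and the gene lengths against the share of the 10 most abundant genes were chosen after that share had been seen, as was the length slope as a term in the fits.

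The breed calls were set against chance, a later slaughter of Churra lambs, length bias and reads shared between similar genes. Of 100 splits of the lambs into 6 and 8, the real one included, 2 gave 26 or more called genes in edgeR. That argues only weakly against chance as the source of that count. The count fell to 0 with Churra 4 left out, and the larger counts given below did not stand out from the splits. The highest other split called 312 genes, and 93 of the 99 other splits called none. That split put Assaf 1, 5, 7 and 8 with Churra 5 and 6, which had a mean score 31.58 higher on the first principal component, a larger mean share of the 10 most abundant genes (32.57% against 24.96%) and a lower mean length slope (-0.0264 against 0.0198) than the other lambs. As 1 split singled out for its high count, it leaves a structure of the samples other than breed only as a possibility. The split with the next highest count called 2 genes and differed by 4.04 on the first component. Which of these measures the counts follow was not tested over the splits. For the 1767 genes at an unadjusted p below 0.05, 7 of the 100 splits gave as many (highest other 2995), and for the 371 genes of DESeq2, 3 of 50 did (highest other 811, median of the others 3), so chance cannot be excluded for those larger counts. A later slaughter of Churra lambs is not enough as the whole cause of the 26 calls, since their log2 fold changes on days 21 to 23 had a median ratio of 1.05 to those in all lambs (quartiles 0.963 and 1.18), although those lambs are part of the same data. With the length slope as a term the median ratio was 1 (quartiles 0.989 and 1.01). The mean slope was nearly equal in the breeds (-0.0027 in Assaf, 0.0036 in Churra), so the term could hardly move these ratios. That fit therefore cannot decide on length bias, and the values show only that the mean slope was alike in the breeds. Of the 26 genes, 1 had a posterior SD above 5% of its count, against 2.3% of all tested genes. A low number was thus likely for any list, and shows only that reads shared between similar genes affected few of these counts. A difference of the breeds themselves stays open as a hypothesis.

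The share of counts in the 10 most abundant genes ranged from 18.0% to 45.2% between lambs. Depth as the main cause is argued against only weakly. The share had r of 0.297 with the total count (permutation p = 0.303), at most 0.411 with 1 lamb left out, and 0.463 within Churra. With 14 lambs, a part played by depth cannot be excluded. The slaughter day found the values it needs as an explanation, with the weaker of the within-breed rho at -0.589 in Assaf (exact permutation p = 0.129), and so did a transcript length bias between libraries (r = -0.811). A hypothesis on what these genes are is that most lie on the mitochondrial genome. Of the 10 genes, 9 had a length equal to the base to that of 1 of the 15 mitochondrial protein-coding or rRNA genes in the RefSeq table of ARS-UI_Ramb_v3.0, against 0.64% of the other 13187 tested genes. The match is by length alone, names no gene, and may not carry over to the build of the files. If it holds, the share would measure mitochondrial transcripts, and a fall of these with the slaughter day and a loss of long transcripts in some RNA samples both remain candidate explanations, since no measure of RNA integrity was used here.

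The slaughter day shows the same difficulty. Of 100 orders of the days within each breed, the real one included, 3 gave 2156 or more genes at an unadjusted p below 0.05. The highest other count was 2571 and the median of the others was 520. That argues only weakly against a chance order of the days, since no gene passed the adjusted threshold. In Assaf lambs only, the count at that unadjusted p was 439. With the length slope as a term the count at that p was 662, against 660 from chance, and without Churra 6 it was 1170. In limma-trend on log2(TPM + 0.5), without scaling between lambs, it was 3794. The share of TPM in the 10 most abundant genes fell with the day, with rho of -0.728 over 14 lambs (permutation p = 0.00419). As TPM sum to the same total in every lamb, that fall alone would raise the values of the other genes. The count of 3794 therefore cannot be read as a stronger day effect. The length slope itself rose with the day, with r of 0.584 (permutation p = 0.0263, adjusted p = 0.0612) and rho of 0.609 (permutation p = 0.0233, adjusted p = 0.0419) over 14 lambs. The r was 0.347 without Churra 1 and Churra 2, 0.338 within Assaf and 0.869 within Churra. A trend of library quality with the day and a change of the tissue that favours short or long genes stay open, and a lamb series with RNA integrity values would be needed to part them. The breed calls went the other way, with 96 genes called once the length slope was a term, among them all 26.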
